A study of Drosophila melanogaster with 24 samples.

How the data were processed

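Poly(A) RNA from fly heads was sequenced for wild type (strain w1118, labelled as the control of the mutant) and for the cwo5073 mutant. Per the labels, flies were kept in 12 h light and 12 h dark at 25 °C for 3 days and collected on day 4; the treatment text names 2 collection times and the titles and design name 6, and the titles were followed. Libraries were made from 1 µg of total RNA with a directional kit and 12 PCR cycles and read as 75 bp single-end reads on a NextSeq. The 24 libraries form 12 groups of genotype and time with 2 replicates each, and no column was left unmapped. Nothing in the labels says whether replicates come from separate fly cultures or collections, so the p-values measure the spread between these samples, taken as independent. Mutant libraries of the same replicate number shared differences (correlated over 0.1 in 14 of 15 pairs of times). The p-values over all times do not cover a spread between such sets of libraries. The sex and age of the flies are not given in the sources used here.

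The submitters' processing notes name STAR 2.6.1d, StringTie and DESeq2, and dm6 as the genome build, with no roles or options. The deposited gene table holds expected counts for 16727 genes, whole numbers that were not normalized. In every library the deposited count of each of the 16722 genes that could be compared equalled the sum, over the gene's transcripts, of coverage times transcript length divided by 75, rounded up. These are estimates from assembled coverage and not reads counted once each, and reads of overlapping models are divided by the submitters' software. Per the file headers, 24 transcript tables give coverage, a signal per base that is not scaled to depth, and FPKM for 35411 transcripts. A second gene table by the authors holds FPKM for 8489 genes; how these were selected is not given in the sources used here.

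Counts per library totalled 11322400 to 19642411. No 2 libraries were identical, and the chi-square per degree of freedom between the replicates of a group was 34.8 to 314, so no pair behaves as technical repeats. Confidence intervals of single shares were not needed because every comparison is between replicated groups; where a gene was at 0 in all libraries of a group, folds are bounds against a floor of 3 counts per library. Such floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Among the gene names 6 had been turned into calendar dates by a spreadsheet program; they were left out of the tests and of the library sizes. Of the gene names, 16503 matched the RefSeq annotation, and 1603 genes had no count in any library. Exon positions of cwo were taken from the Ensembl gene models by exon number and length.

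Gene counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr on the 12 groups, which left 11095, and scaled by TMM. Differences between genotypes came from edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) on a 12-level group factor without a replicate term, with p-values adjusted by Benjamini-Hochberg and a threshold of 0.05. The contrast over all times was the mean of the 6 mutant groups minus that of the 6 wild-type groups. Each time was also tested by itself, with the spread shared over all groups, and the 5 terms of the genotype by time interaction were tested together. The common biological coefficient of variation was 0.26. Log2 fold changes and their SE are those of the edgeR fit, which averages log values over times, so they can differ from the ratio of mean CPM.

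Rhythms were tested in edgeR with a genotype intercept and a cosine and a sine of a 24 h period for each genotype: the wild-type pair, the mutant pair and their difference. Amplitude and peak time, with SE by the delta method, came from least squares on log2 CPM. Only the 24 h harmonic was fitted, and a single day says nothing about the period. Gene lists were tested with limma's camera (preset correlation 0.01, adjusted over 32 lists with at least 3 members), which compares a list with the other genes; camera with an estimated correlation and fry were run beside it. The estimated correlation left 3 list calls: the core clock, the evening E-box and the pigment cell and lens lists. The genes w and cwo each stand in 2 lists. Transcripts with FPKM of at least 1 in at least 2 libraries were tested with limma (trend) on log2(FPKM + 1). Correlations used permutation tests with 100000 resamples in R. Tables were joined with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3), and figures were drawn with matplotlib 3.10.9.

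The comparisons, the lists and the rule for naming genes were set before the data were examined. Named genes are cwo, all measured core clock genes, and, at an adjusted p under 0.05 and an average log2 CPM of at least 3, the 10 highest and 10 lowest fold changes over all times with the same sign at all 6, the 2 highest and 2 lowest at each time, and the 10 (wild type) and 5 (mutant) largest amplitudes. The 10 genes with the lowest p for the difference in rhythm and the 5 with the lowest for the interaction were added, as were the 2 highest and 2 lowest called members of each list and the transcripts of 7 clock genes. Mitochondrial genes, rRNA and tRNA were passed over. Other genes are said to have been chosen after their values were seen. Where overlapping partners are named for genes on shared loci, these too were chosen after.

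The steps were tested on simulated counts for the 11095 genes with the real library sizes and dispersions. Of 200 genes changed by 1 on the log2 scale edgeR recovered 85.5% over all times and 29% at ZT2; at a change of 2 it recovered 96.5% and 81%. For wild-type rhythms it recovered 45% at an amplitude of 0.5 and 82% at 1. For a rhythm lost in the mutant, the difference test found 11% and 65%, and the interaction test 35% at an amplitude of 1. False calls were at most 4.51% of the calls of edgeR. The simulated libraries held no library that stands apart, no dependence on gene length and no differences shared between libraries. These shares are therefore no false call rates for the real genes. With DESeq2 they were 10.3% to 14.9% for differences and rhythms and 45.9% for the interaction, so its higher counts are given only as an alternative. Of 30 random lists camera and fry called 0 at an adjusted p under 0.05, while both called the list that was moved. The simulated genes were drawn independently of each other. This result therefore gives no false call rate for real lists whose genes move together, where the estimated correlation reached 0.796 (cytosolic ribosomal proteins).

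Alternatives were RLE scaling, no filter or a mean CPM of at least 5, DESeq2 1.42.0, limma-voom, limma on gene FPKM with a pseudocount of 1 or 0.1, a replicate block, an adjusted p under 0.01, a log2 limit of 1, an amplitude limit of 0.5, time as a factor, single genotypes, times or replicate numbers, and leaving out each library. Chosen after seeing the data were gene length offsets (a lowess on log2 gene length per library), leaving out the pair of wild-type libraries with the lowest length score, averaging only ZT6 to ZT18, leaving out genes at 0 in some libraries and at 10 CPM or more in others, and lists without cwo and w. No genome sequence was used, so base composition and the mutant allele were not analysed here, and no raw reads were used here.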

Results

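Heads of wild-type flies (strain w1118) and of cwo5073 mutant flies were compared at 6 times of the light-dark day, given as zeitgeber time (ZT, hours after lights on). The gene cwo (clockwork orange) encodes a transcriptional repressor of the circadian clock, and the comparison asks how the mutant changes the level and the daily course of clock genes and of other head transcripts. Each genotype and time had 2 libraries, with 11322400 to 19642411 counts per library, and 11095 genes were tested. The opsin gene ninaE took the largest share of counts in every library, 1.68% to 4.67%.

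The wild-type ZT2 replicate 2 library stood apart from the others: its median Spearman correlation with the other libraries was 0.933, against 0.965 to 0.979 for the remaining 23. Its long transcripts were also low relative to its short ones. The median log2 deviation of long abundant genes minus that of short ones was -1.34 in this library and -1.19 in wild-type ZT22 replicate 1. The mutant libraries lay between -0.44 and 0.56 on this score. Across genes, transcript length and the mutant minus wild-type log2 fold change had a Spearman rho of 0.43 over all times, 0.51 at ZT22 and -0.01 at ZT18; genes are not independent replicates.

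**Figure D1:**
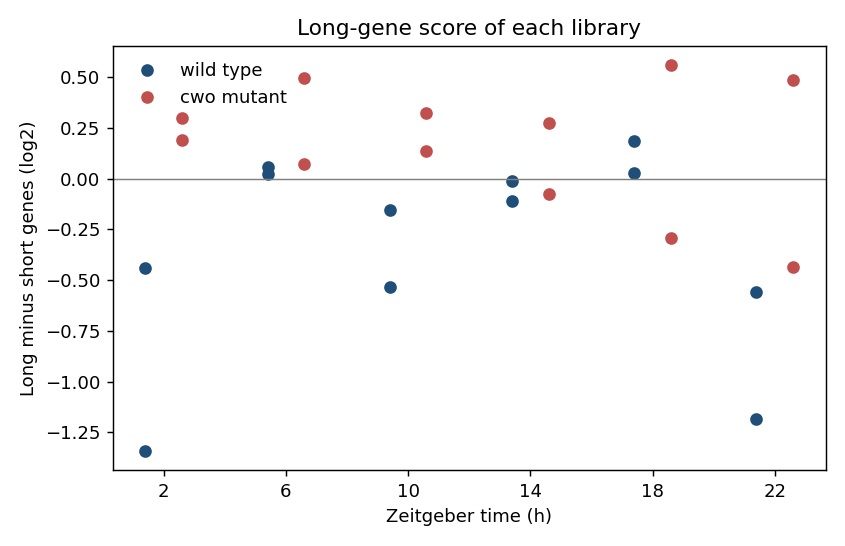
Difference between long and short genes (median log2 deviation from the median library) for each of the 24 libraries, by time in hours (ZT) and genotype; each point is 1 library. Wild-type ZT2 replicate 2 (-1.34) and wild-type ZT22 replicate 1 (-1.19) lie lowest.

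The cwo transcript itself was more abundant in the mutant. Its library-size-scaled counts (CPM) averaged 93.5 ± 39.6 in wild type and 523 ± 247 in the mutant (SD over the 12 libraries of each genotype), a log2 fold change of 2.44 ± 0.07 (SE; adjusted p = 8.8e-12). All 12 mutant libraries, from 242 CPM up, lay above the highest wild-type library at 174 CPM. The log2 difference was 1.81 at ZT6, the lowest of the 6 times, and 2.96 at ZT18, the highest. The gene lies on chromosome 3R from 10388258 to 10400752.

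Transcript FPKM moved to 1 of the 3 annotated cwo transcripts. The transcript of 5092 nt held 32.4 ± 24% of the cwo FPKM in wild type and 97.0 ± 3.1% in the mutant (SD, n = 12), and rose from 5.34 to 93.7 FPKM (log2 fold change 3.92 ± 0.24, adjusted p = 1.3e-07). The transcript of 4632 nt fell from 11.3 to 1.18 FPKM (log2 fold change -2.14 ± 0.43, adjusted p = 0.00826). The third, of 4508 nt, averaged 2.40 FPKM in wild type and 1.5 in the mutant (log2 fold change -0.46 ± 0.44, adjusted p = 0.531). The longest form carries an exon 2 of 584 nt (10396237 to 10396820), which the middle form carries only as its last 124 nt and the shortest form lacks. Reads were divided between these overlapping models by the submitters' software, so the shares rest on that division.

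**Figure D2:**
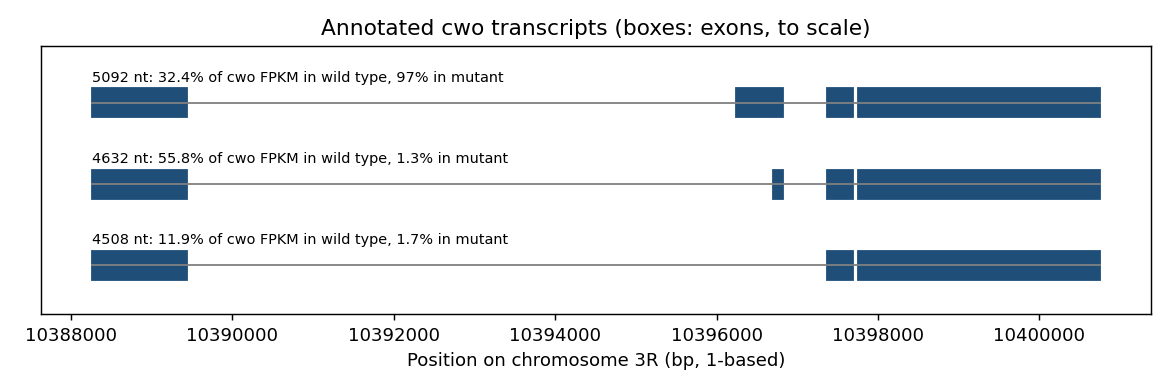
Exons (boxes, to scale) of the 3 annotated cwo transcripts by position on chromosome 3R (bp), with the share of the cwo FPKM (%) each held on average over the 12 libraries of a genotype. The 5092 nt form held 97.0% in the mutant and 32.4% in wild type.

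Of the 19 core clock genes measured, 6 rose in the mutant over all times and none fell. Clk, the activator of the loop, rose from 33.5 to 48.6 CPM (log2 fold change 0.65 ± 0.11, adjusted p = 5.1e-04). The repressor gene tim rose by 0.46 ± 0.10 (adjusted p = 0.00517), and CG31324, the fly ortholog of CIPC that the study's title names, by 0.57 ± 0.08 from 72.5 to 108 CPM (adjusted p = 1.1e-04). The repressor gene vri rose by 0.49 ± 0.16 (adjusted p = 0.0314) and the phosphatase subunit gene tws by 0.21 ± 0.07 (adjusted p = 0.0464); these calls ended in 14 and 24 of 34 alternative settings, and that of tim in 1. No change was called for per (0.16 ± 0.12), Pdp1 (0.01 ± 0.17), cyc, cry, dco, jet, slmb, sgg, CkIIalpha, CkIIbeta, nmo, mts or wdb. The same 6 genes passed when p-values were adjusted over the list alone.

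At single times, tim and vri stood out at ZT2 and ZT22 and Clk at ZT14. At ZT2 tim was higher in the mutant by 1.39 ± 0.25 (SE; adjusted p = 0.0093) and vri by 1.43 ± 0.39 (adjusted p = 0.0373). This comparison holds the wild-type library that stands apart. Without it the changes were 1.20 ± 0.31 for tim and 0.83 ± 0.33 for vri, and without wild-type ZT2 replicate 1 they were 1.58 ± 0.31 and 2.49 ± 0.37. Without mutant ZT2 replicates 1 and 2 the change was 1.34 and 1.40 for tim and 1.18 and 1.61 for vri. Each of these fits leaves 1 library in a group, and both calls were kept only without wild-type ZT2 replicate 1. At ZT22 vri was higher by 1.43 ± 0.39 and tim by 0.84 ± 0.25 (adjusted p = 0.105 and 0.132 over all genes, and 0.0209 for both over the list alone). Clk was higher at ZT14 by 1.42 ± 0.27 (adjusted p = 0.0189). Without wild-type ZT14 replicates 1 and 2 this change was 1.85 and 1.08, and without the mutant ones 1.65 and 1.18. The Clk call was lost without replicate 2 of either genotype. CG31324 passed over the list alone at ZT6, ZT14, ZT18 and ZT22, and over all genes at no single time. The interaction of genotype and time, adjusted over all genes, did not pass for any of them (adjusted p = 0.903 for Clk, tim and vri, 0.932 for CG31324).

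**Figure D3:**
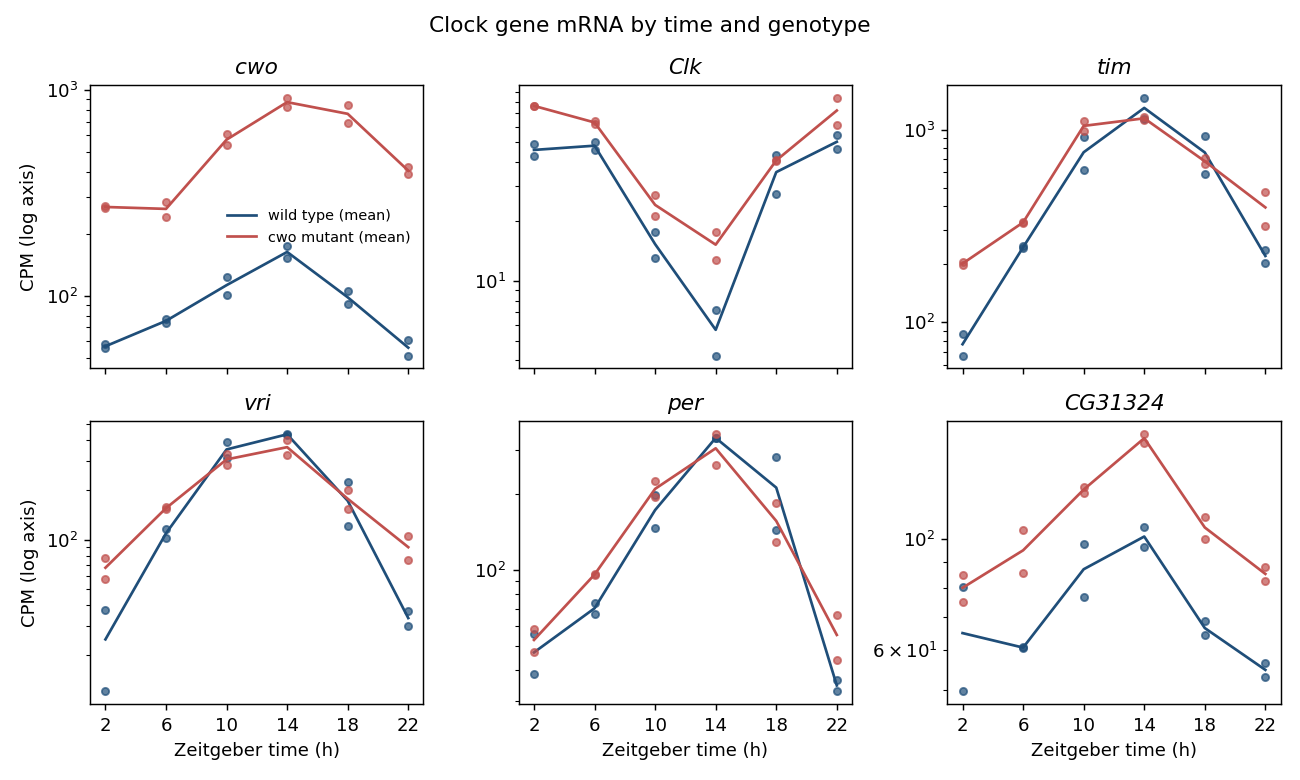
CPM (log axis) of clock genes by time (ZT, h) in wild type and mutant; points are single libraries and lines join the means of 2. The troughs of tim and vri are shallower in the mutant, at ZT2 by less without wild-type ZT2 replicate 2, and cwo lies above wild type at all 6 times.

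Among all tested genes, clock genes included, 3104 (28%) differed between the genotypes over all times, 1566 higher and 1538 lower in the mutant. Limma on gene FPKM, on fewer genes, called 734 higher and 1298 lower with a pseudocount of 1 and 693 and 1269 with 0.1. The median size of the called changes was 0.474 on the log2 scale, and 1662 of the genes changed by less than 0.5. At least 2-fold changes were seen in 279 higher and 213 lower genes. The p-values take the libraries as independent, while mutant libraries of the same replicate number shared differences over the times. Leaving out wild-type ZT2 replicate 1 gave 5592 genes, and averaging only ZT6 to ZT18 gave 789.

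Among the genes that rose most, CG8147 on 3R (9494801 to 9496723), within 2000000 bases of cwo, went from 24.4 to 755 CPM (log2 fold change 5.18 ± 0.22, adjusted p = 2.0e-10). The eye pigment transporter gene w rose from 10.1 to 277 CPM (4.66 ± 0.18, adjusted p = 9.1e-11) and CG13646 from 1.11 to 15.5 CPM (3.89 ± 0.14). For these 3 genes every mutant library lay above every wild-type library. The storage protein gene Lsp2 rose by 4.41 ± 0.87 (adjusted p = 0.00259), with mutant libraries at 36.3 to 409 CPM in replicate 1 and at 4.82 to 34.5 in replicate 2. CG34166, CG4757, CG11425 and CG15068 rose by 3.63, 3.09, 3.04 and 2.85. The non-coding CR45396 rose by 2.91 ± 0.66 (adjusted p = 0.00605), and beta4GalNAcTB by 3.85 ± 1.34 (adjusted p = 0.0477), a call that ended in 25 of 34 alternatives. The overlapping CR45044 on the other strand averaged 19.8 CPM where beta4GalNAcTB was at 0 and 5.64 elsewhere. The division of reads between these models leaves the changes of both uncertain.

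Among genes at an average log2 CPM of at least 3, the strongest loss was in the cytochrome P450 gene Cyp6a17 (2R, 14873953 to 14875739), which averaged 96.8 CPM in wild type and 0.286 in the mutant. With both mutant libraries at 0, it was at least 442-fold lower at ZT10 and at least 801-fold lower at ZT22, against a floor of 3 counts per library. Its closely similar neighbouring copy Cyp6a23, chosen after its values were seen, went from 15.1 to 26.9 CPM (log2 fold change 0.84 ± 0.17), so the split of reads between the copies is uncertain. CG12947 and MtnA, adjacent on 3R between 9780064 and 9784370, fell by 5.11 ± 0.20 and by 2.42 ± 0.20 (log2, SE); the metallothionein gene MtnA went from 918 to 155 CPM (adjusted p = 6.1e-07). CG10936 fell by 4.39 ± 0.15 from 88.0 to 4.13 CPM, CG6084 by 2.98 ± 0.16, and the pteridine gene se by 2.77 ± 0.18 from 271 to 38.6 CPM. Arc1, a capsid-like gene of neurons, fell by 2.07 ± 0.22 from 1019 to 236 CPM (adjusted p = 1.0e-05). CG9150 and CG5391 fell by 2.22 and 2.00. For all of these but CR45044, which overlaps beta4GalNAcTB and fell by 4.12 ± 1.44 (adjusted p = 0.0482; the call ended in 20 of 34 alternatives), every mutant library lay below every wild-type library.

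Part of the genes of the humoral immune response were higher in the mutant, and their lists passed with the preset correlation but not with an estimated one. Of 27 antimicrobial peptide genes, 16 rose and 2 fell (17 and 2 adjusted over the list alone; list adjusted p = 4.4e-08, and adjusted p = 0.438 with an estimated correlation). AttC rose by 3.34 ± 0.54 (SE; adjusted p = 4.7e-04), from 20.9 to 40.3 CPM; the wild-type mean is carried by the 2 ZT18 libraries at 78.3 and 151 CPM. Def was at 0 in both wild-type ZT10 libraries and at least 15.1-fold higher in the mutant there. AttA fell by 1.82 ± 0.39 and CG5791 by 0.52 ± 0.18, the latter call ending in 22 of 34 alternatives. Among 29 immune recognition and signalling genes 10 rose and 1 fell (11 and 2 over the list alone; adjusted p = 0.00689, and adjusted p = 0.644 with an estimated correlation), with TotM up by 2.32 ± 0.41 and TotC by 2.09 ± 0.32, and imd down (-0.32 ± 0.10, ended in 16 of 34 alternatives). The AttC mean was 63.2 CPM in the mutant libraries numbered replicate 1 and 17.5 in those numbered replicate 2.

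Many fat body genes rose too, some of them, with the yolk protein genes and CG6188 among these, mainly in the mutant libraries numbered replicate 1. Of 27 fat body genes, 15 rose and 1 fell (18 and 2 over the list alone; adjusted p = 6.8e-04, and adjusted p = 0.644 with an estimated correlation). CG6188 (Gnmt) rose by 2.58 ± 0.53, with a mean of 98.4 CPM in mutant replicate 1 and 20.05 in mutant replicate 2, against 12.7 and 10.9 in wild type. The gene tobi fell by 2.19 ± 0.25. Yp1 rose by 1.47 ± 0.40 (adjusted p = 0.0153) and Yp2 by 1.64 ± 0.49 (adjusted p = 0.024). Yp1 lay at 16930 to 26180 CPM in the mutant libraries of replicate 1 and at 4549 to 7248 in those of replicate 2, against 2106 to 11430 over the wild-type libraries of replicate 2 and 4454 to 8505 over those of replicate 1. Yp2 averaged 12670 CPM in mutant replicate 1 and 2620 in mutant replicate 2, against 3018 and 2411 in wild type, and its call ended in 11 of 34 alternatives. The female biased list, 5 genes of which 4 rose, did not pass (adjusted p = 0.0545, and adjusted p = 0.664 with an estimated correlation). For the 5 male biased genes 2 rose and 1 fell (adjusted p = 0.178), with sxe2 up by 0.69 ± 0.08 and roX2 down (-0.52 ± 0.17, ended in 13 of 34 alternatives). The mean of roX2 was 19.0 CPM in mutant replicate 1 and 30.5 in mutant replicate 2, against 33.1 and 41.9 in wild type.

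Clock-related, lens and glial lists passed upward with the preset correlation, where the core clock call needed cwo and the lens call needed w. The core clock list passed with adjusted p = 5.5e-04 (0.0218 with an estimated correlation, 0.0564 with gene length offsets) and the 6 evening E-box genes, of which 4 rose, with 1.8e-08 (0.00561 with an estimated correlation). Without cwo and w, a pair of genes left out after their values were seen, these became adjusted p = 0.131 and 0.038 (0.422 and 0.279 with an estimated correlation). Of 23 head rhythm output genes, 8 rose and 1 fell (10 and 2 over the list alone; adjusted p = 0.0337, adjusted p = 0.243 with an estimated correlation and 0.116 with gene length offsets): CG11891 rose by 1.22 ± 0.10 and CG17386 by 1.01 ± 0.16, and CG10553 fell by 1.17 ± 0.14. The 5 pigment cell and lens genes, with w and retinin (0.50 ± 0.16) higher, passed with adjusted p = 5.5e-04 (0.032 with an estimated correlation) and no longer did without w (adjusted p = 0.949). The retinin call ended in 12 of 34 alternatives; its mean was 1343 CPM in mutant replicate 2, against 778 in mutant replicate 1 and 790 and 733 in wild type. Of 18 glial genes 6 rose, among them axo by 1.02 ± 0.10 and e by 0.62 ± 0.11 (10 rose and 1 fell over the list alone; adjusted p = 0.00215, adjusted p = 0.437 with an estimated correlation and 0.0564 with gene length offsets).

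Part of the muscle, heat shock and cuticle transcripts were lower in the mutant, and their lists passed with the preset correlation but not with an estimated one. Of 22 muscle genes 10 fell and none rose (11 over the list alone; adjusted p = 3.5e-04, and adjusted p = 0.0905 with an estimated correlation), with TpnC41C (-0.92 ± 0.16) and Mf (-0.78 ± 0.11) among them. Of 20 heat shock and chaperone genes 12 fell (12 over the list alone, where 1 also rose; adjusted p = 0.00113, and adjusted p = 0.142 with an estimated correlation); Hsp27 fell by 2.05 ± 0.21 and Hsp22 from 51.7 to 15.9 CPM. Of 45 cuticle protein genes 15 fell and 3 rose (17 and 3 over the list alone; adjusted p = 4.3e-04, and adjusted p = 0.422 with an estimated correlation). Among the cuticle genes, at under 4 CPM, Cpr78Ca fell by 3.70 and Cpr49Ah by 1.94, while Cpr72Eb rose by 2.58 and TwdlE by 1.51.

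Peptide hormone genes passed downward as a list as well, with the preset correlation only in camera's test. Of 30 neuropeptide genes 15 fell and 3 rose (17 and 4 over the list alone; adjusted p = 0.00301, and adjusted p = 0.484 with an estimated correlation). The insulin-like gene Ilp3 went from 19.8 to 7.42 CPM (log2 fold change -1.40 ± 0.21, SE) and Trissin from 66.1 to 39.6 CPM (-0.65 ± 0.15), while CG13936 (CNMa) rose by 0.89 ± 0.16 and Dh44 by 0.43 ± 0.14. The Dh44 call ended in 19 of 34 alternatives, and the list call with gene length offsets (adjusted p = 0.286).

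Mitochondrial, proteasome and glutathione transferase lists were lower with the preset correlation, by amounts that moved with a correction for gene length. Of 71 nuclear oxidative phosphorylation genes 20 fell and 1 rose (25 and 1 over the list alone; adjusted p = 1.8e-05, and adjusted p = 0.674 with an estimated correlation), among them CG34172 (-0.99 ± 0.23, SE) and CG11455 (-0.70 ± 0.21, ended in 11 of 34 alternatives). Of 73 mitochondrial ribosomal protein genes 18 fell (18 over the list alone; adjusted p = 1.8e-05, and adjusted p = 0.674 with an estimated correlation), such as mRpL49 (-0.59 ± 0.20, ended in 20 of 34 alternatives) and mRpL52 (-0.57 ± 0.16). Of 38 proteasome genes 9 fell and 1 rose (8 and 1 over the list alone; adjusted p = 0.0439, and adjusted p = 0.674 with an estimated correlation), such as Prosalpha5 (-0.49 ± 0.12) and Prosbeta4 (-0.45 ± 0.11). Of 31 glutathione S-transferase genes 10 fell and 2 rose (11 and 2 over the list alone; adjusted p = 0.00689, and adjusted p = 0.674 with an estimated correlation), with GstE14 at -0.97 ± 0.12 and GstD9 at -0.87 ± 0.14. With gene length offsets the adjusted p of these lists was 0.0343, 0.158, 0.859 and 0.685. At ZT6 to ZT18 alone it was 0.143, 0.253, 0.636 and 0.143. The named oxidative phosphorylation and mitochondrial ribosomal genes differed most at ZT2, the time of the wild-type library that stands apart: the log2 fold change there was -2.30 for CG34172, -2.01 for CG11455, -2.04 for mRpL49 and -1.92 for mRpL52, against 0.02, 0.24, 0.12 and 0.07 at ZT18. Without that library their changes over all times were -0.79, -0.47, -0.35 and -0.38.

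Several other lists held strong changes in single genes without passing camera's test. The phototransduction genes inaF-B and trp rose from 1040 to 1990 and from 3856 to 5805 CPM (log2 fold changes 0.95 ± 0.08 and 0.60 ± 0.09, SE), while Gprk1 (-0.41 ± 0.09) and Rh6 (-0.38 ± 0.09) fell; 7 of 33 rose and 2 fell (adjusted p = 0.34, and 0.0256 upward with fry). In the eye pigment list 4 of 19 rose and 5 fell (4 and 6 over the list alone; adjusted p = 0.811): v rose by 0.87 ± 0.17, and the GTP cyclohydrolase gene Pu fell by 1.51 ± 0.12 from 728 to 253 CPM. Of 20 UDP-glycosyltransferase genes 9 rose and 4 fell (adjusted p = 0.694); Ugt86Dd fell by 1.58 ± 0.13 and Ugt86Di by 4.96 ± 0.34, while CG5999 and Ugt86Dg, both under 1 CPM, rose. Of 71 detoxification P450 genes 11 rose and 9 fell (adjusted p = 0.833), with Cyp6a2 up by 1.94 ± 0.16 and Cyp6a19 down (-2.12 ± 0.35); the list's median was 0.0047 and its mean -0.04. Of 33 odorant binding protein genes 3 rose, among them Obp99b (1.17 ± 0.27), and 5 fell, among them Obp56h (-1.36 ± 0.19) and Obp19b (-1.01 ± 0.15; list adjusted p = 0.153). The activity regulated gene Hr38 rose by 0.63 ± 0.20, ended in 11 of 34 alternatives, and puc by 0.35 ± 0.09, in a list of 9 with 2 up and 1 down (adjusted p = 0.642).

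Neuronal genes moved in both directions. In the synaptic list brp (0.58 ± 0.19, SE) and futsch (0.51 ± 0.16) were higher and nrv3 (-0.75 ± 0.22; -0.47 without wild-type ZT2 replicate 2) and Rdl (-0.57 ± 0.17) lower, 4 of 28 up and 2 down (adjusted p = 0.694); the brp, futsch and nrv3 calls ended in 20, 10 and 4 of 34 alternatives. The Rdl call was kept, with changes from -0.863 to -0.315. Its highest wild-type library was at 2913 CPM in replicate 2, against 940 in replicate 1. Of 24 neuropeptide and amine receptor genes 3 rose (1 over the list alone; adjusted p = 0.178), including mAChR-A (0.41 ± 0.10). The direction of the synaptic, receptor, activity regulated, P450, odorant binding protein, ovary and testis, and cytosolic ribosomal protein lists flipped under gene length offsets or with ZT6 to ZT18 alone. None of those lists passed. Of 77 odorant, gustatory and ionotropic receptor genes 11 rose and 4 fell (9 and 3 over the list alone; adjusted p = 0.0683, and 0.0226 with gene length offsets), with Or45a down (-1.17 ± 0.32; -0.66 without wild-type ZT2 replicate 2, where it was at 106 CPM against 6.69 in replicate 1).

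The remaining lists did not pass. Of 87 cytosolic ribosomal protein genes 1 rose and 1 fell, RpL24-like by -0.45 ± 0.13 (SE; ended in 5 of 34 alternatives; list adjusted p = 0.0717). Of 35 lipid and sugar genes 9 rose and 4 fell (adjusted p = 0.156); the hexokinase gene Hex-C rose by 0.94 ± 0.19 and Amy-p fell by 1.36 ± 0.37. Of 10 gut enzyme genes 2 rose and 2 fell (adjusted p = 0.811), with a median of 0.21, a mean of -0.15 and an upward test direction. In the list set for the Hairy and E-spl family, to which cwo is related, h rose by 0.64 ± 0.08 (adjusted p = 5.9e-05) and Hey by 0.96 ± 0.25, and Max, a partner of Myc outside this family that the list also holds, was lower (-0.34 ± 0.10, ended in 12 of 34 alternatives); 2 of 10 rose and 1 fell, with a median of -0.06, a mean of 0.15 and adjusted p = 0.694. None of the 6 ovary and testis transcripts passed in edgeR (list adjusted p = 0.949); loqs was the nearest (-0.18 ± 0.07, adjusted p = 0.0535).

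At single times the number of genes that differed was highest at ZT2. There 1609 genes passed, 564 higher and 1045 lower in the mutant, against 92 at ZT6, 140 at ZT10, 90 at ZT14, 84 at ZT18 and 129 at ZT22. The excess of lower genes was not seen with limma-voom (325 higher, 254 lower), with limma on FPKM (59.2% higher), without wild-type ZT2 replicate 1 (3040 and 2694) or without replicate 2 (50 and 47). Without wild-type ZT2 replicate 2 the ZT2 count was 97, and without wild-type ZT2 replicate 1 it was 5734. Leaving out a mutant ZT2 library gave 66 or 80. Of the genes called at ZT2, 1459 were called at no other time. At all 6 times 45 genes passed, 23 higher and 22 lower; 20 of them lie on 3R (44.4%, against 24.7% of all tested genes; Fisher's exact test, two-sided, p = 0.0047). Of all genes changed at least 2-fold over all times, cwo left aside, the share was highest on 2R (6.53% of its genes, against 5.15% on 3R).

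**Figure D4:**
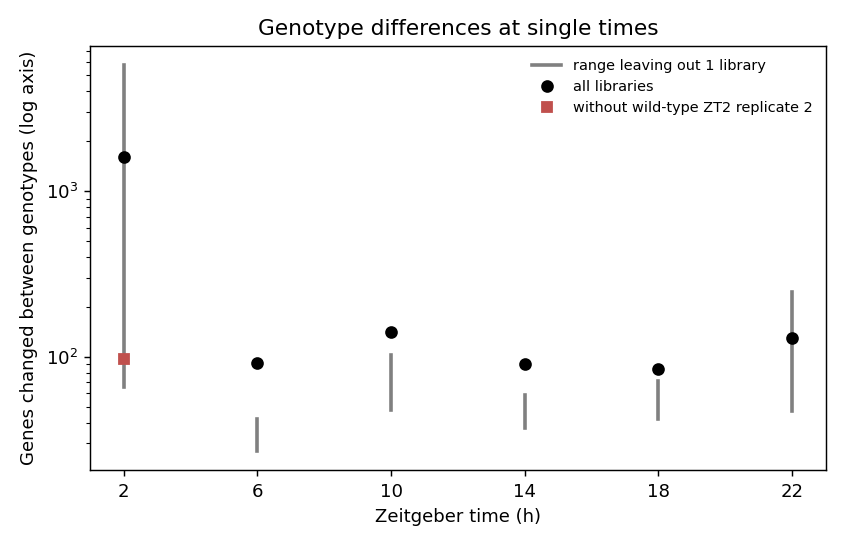
Number of genes (log axis) that differed between the genotypes at each time (ZT, h) at adjusted p under 0.05, with all libraries (black points), as the range when 1 library of that time is left out (grey lines) and without wild-type ZT2 replicate 2 (red square). ZT2 has 1609 genes and the other times 84 to 140.

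At an average log2 CPM of at least 3, large changes at single times belonged to w, CG8147, Cyp6a17, CG12947 and CG10936, and to some gene models that share a locus. At ZT14 w was higher by 5.88 ± 0.46 (SE; adjusted p = 5.6e-06), and at ZT22 CG8147 by 6.36 ± 0.56 (adjusted p = 1.2e-05). CG10936 was lower at ZT6 (-4.84 ± 0.39) and CG12947 at ZT14 (-5.69 ± 0.49). The non-coding CR45142, whose span on 2R (13168500 to 13170745) overlaps that of Spt-I (13168498 to 13170744), was higher at ZT22 by 6.31 ± 1.06 (adjusted p = 0.00527; the call ended in 4 of 14 alternatives).

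Further calls at ZT2 and ZT10 fall on loci where 2 gene models have the same start and end. The gene ssp2 was at 0 in both wild-type ZT2 libraries and at 87.0 CPM in the mutant, while Nxf3 on the same span held 71.6 and 4.07 CPM in wild type. CG17327 was at 0 in the mutant at ZT2, where CG44194 held 30.6 and 33.2 CPM. Tim9b was at 0 in wild type at ZT10, where CG12788 held 18.9 and 21.5 CPM. The counts of stnB were 1.16 and 0 CPM in wild type at ZT10, where stnA held 553 and 544 CPM. Reads of such loci can be assigned to either model, so these changes are uncertain. The calls of ssp2, CG17327, Tim9b and stnB ended in 5, 6, 5 and 5 of 14 alternatives.

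The test of genotype by time found no gene in edgeR at an adjusted p under 0.05, with 267 genes at an unadjusted p under 0.05; DESeq2 called 26, limma on FPKM 3 or 4 and limma-voom 0. The lowest p-values were those of rgr (2.1e-04), CR44390, CG31683, cv-2 and CG31871. Without wild-type ZT2 replicate 1 the edgeR count was 2106.

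Daily rhythms were called in 623 genes in wild type and in 121 in the mutant when all 24 libraries were fitted together. Fitting the 12 libraries of each genotype by themselves gave the other order, 128 in wild type and 265 in the mutant, so the counts do not show which genotype has more rhythmic genes. Among clock genes, vri had the widest wild-type rhythm, with an amplitude (the fitted distance from mean to peak, log2) of 2.26 ± 0.21 and a peak at ZT 12.6 (adjusted p = 5.2e-08). In the same genotype tim (1.92 ± 0.15, peak 13.9 h), per (1.61 ± 0.20, 13.5 h), Clk (1.42 ± 0.29, 1.03 h), cwo (0.76 ± 0.07, 13.1 h), CG31324 (0.39 ± 0.10, 12.5 h) and tws (0.37 ± 0.06, 11.1 h) were rhythmic. In the mutant the same set except tws passed, and cry joined it (0.80 ± 0.06, peak 5.11 h, adjusted p = 0.00133; wild-type adjusted p = 0.0623). Among genes outside the clock called rhythmic at an average log2 CPM of at least 3, the largest wild-type amplitudes were those of CG17005 (2.88 ± 0.31, peak 8.20 h), CG44194 (2.54 ± 1.01), CG17386 (2.52 ± 0.46), CG34134 (2.45 ± 0.23, 22.5 h), cyr (2.11 ± 0.12, 14.1 h), CG17075 (2.10 ± 0.52), AttC (2.03 ± 0.81) and Myo28B1 (1.82 ± 0.26). Among genes called in the mutant, under the same limit, CG17005 (2.80 ± 0.40), CG34134 (2.00 ± 0.15) and cyr (1.64 ± 0.11) led.

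Some of the wild-type calls rest on fewer libraries or settings. CG17075 lost its call in 18 of 34 alternatives, AttC in 4, and CG44194 shares its locus with CG17327. The wild-type count was 383 without wild-type ZT22 replicate 1 and 1097 without wild-type ZT2 replicate 1; the mutant count was 212 without wild-type ZT2 replicate 2. Peaks in wild type were most frequent near ZT0 (158 genes) and ZT12 (126) and fewest near ZT8 (54). The 2 wild-type libraries with the lowest long minus short gene score lie on either side of ZT0, at ZT22 (-1.19) and ZT2 (-1.34). Whether the peak times follow this score was not tested, so the distribution need not be biological. In the mutant each 4 h bin held 13 to 24 genes.

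Both genotypes called 95 genes, where 6.8 would overlap by chance. For these the median absolute difference in peak time was 0.86 h, 83 differed by less than 2 h and 1 by 4 h or more. Their median amplitude was 0.81 in wild type and 0.72 in the mutant. Of the 623 wild-type rhythmic genes 583 had a smaller fitted amplitude in the mutant, a count that selection on the wild-type test favours. That 528 genes were called in wild type alone and 26 in the mutant alone does not show that their rhythms differ.

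The direct test of the difference in rhythm called no gene over all genes in edgeR, with 550 genes at an unadjusted p under 0.05 where 555 would be expected by chance. DESeq2 called 9 and limma-voom and limma on FPKM 0. Adjusted over the core clock list alone, 3 genes passed: vri, whose amplitude was 1.23 ± 0.09 in the mutant (SE; adjusted p = 0.00635), tim at 1.25 ± 0.11 (adjusted p = 0.0434) and cwo, whose amplitude was 0.95 ± 0.06 and whose peak lay at ZT 15.2 ± 0.23 against 13.1 ± 0.37 in wild type (adjusted p = 0.00604). The rhythm of per, at 1.33 ± 0.10 in the mutant, did not differ by this test (unadjusted p = 0.271). The adjustment over the core clock list alone was not repeated without wild-type ZT2 replicate 2. Adjusted over the 649 genes rhythmic in either genotype, 9 genes passed. This selection by the rhythm tests favours differences: 193 of the 623 wild-type rhythmic genes had an unadjusted p under 0.05, where 31.2 would be expected. The 9 genes were CG31268, Ubpy, w, cv-2, CG14186, cwo, snoRNA:Tudor-SN-a, CG32795 and vri. CG31268 and snoRNA:Tudor-SN-a were named after their values were seen.

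Of these, Ubpy (Usp8) peaked at 13 h in wild type and at 10.9 h in the mutant (unadjusted p = 6.0e-05), and CG14186 at 10.3 and 6.51 h. The amplitude of cv-2 was 0.83 ± 0.11 in wild type and 0.24 ± 0.07 in the mutant. The gene w had an amplitude of 0.20 ± 0.21 in wild type and of 0.95 ± 0.09 in the mutant, with a mutant peak at ZT 15.5. Over the 12 mutant libraries w and cwo correlated with Pearson r = 0.974 (permutation p = 1e-05, the smallest that 100000 resamples can give) and Spearman rho = 0.986 (permutation p = 1e-05). Without the 2 farthest libraries r was 0.967. Over the 12 wild-type libraries r was -0.16 (permutation p = 0.628), rho was 0 (p = 1) and r without the 2 farthest libraries was 0.019. These 2 relations were the ones computed, with Benjamini-Hochberg adjusted p = 2e-05 and 0.628 for Pearson's r.

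**Figure D5:**
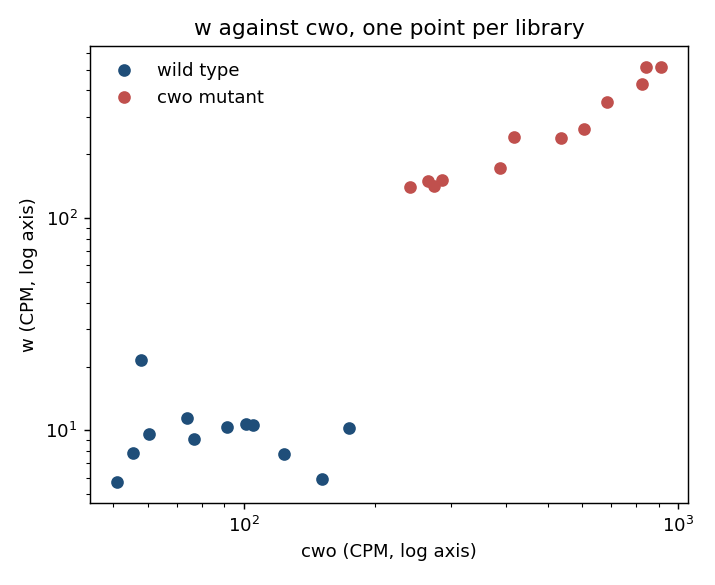
CPM of w against that of cwo (both on log axes), 1 point per library, by genotype. Over the mutant libraries Pearson's r was 0.974, and over the wild-type libraries -0.16.

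At the level of single transcripts, 1676 of 21548 differed between the genotypes over all times, 751 higher and 925 lower in the mutant. Besides cwo, the clock gene Pdp1 had 2 transcripts that rose, of 4702 nt (8.18 to 15.8 FPKM, log2 fold change 1.16 ± 0.24, adjusted p = 0.00942) and of 4643 nt (13.2 to 22.1 FPKM, 1.06 ± 0.22, adjusted p = 0.00994), while no change was called for the gene as a whole. A tim transcript of 5020 nt rose from 0.0677 to 1.72 FPKM (log2 fold change 0.83 ± 0.17, adjusted p = 0.00981). No transcript of CG31324, Clk, per or vri passed; the CG31324 transcript of 1885 nt came nearest (1.29 ± 0.38, adjusted p = 0.0558).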

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

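The tests of w chosen only after the result was seen are its correlation with cwo and the median of the other eye pigment genes; the tests of rhythm differences and the splits of the libraries were planned.

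The daily course of 3 clock genes differed between the genotypes when p-values were adjusted over the core clock list alone. The adjusted p was 0.0434 for tim, 0.00635 for vri and 0.00604 for cwo, all in edgeR. The amplitudes of tim and vri were smaller in the mutant (1.25 against 1.92 and 1.23 against 2.26 on the log2 scale), and cwo peaked at ZT 15.2 against 13.1. Over all 11095 genes none of these 3 passed. The ZT2 difference of vri was 0.83 without wild-type ZT2 replicate 2, the library that stands apart, and 2.49 without replicate 1. For tim these values were 1.20 and 1.58. The adjustment over the list alone was not repeated without that library.

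Adjusted over the genes rhythmic in either genotype, a selection that itself favours differences, 9 genes passed the test of a difference in rhythm. Over all genes none did in edgeR, with 550 at an unadjusted p under 0.05, and DESeq2 called 9. Of the splits of the libraries that exchange genotype labels within each time, all 80 must give at least the real count of 0, so they say nothing about it. By genes at an unadjusted p under 0.05, 24 of the 80 splits, the real one included, gave as many as the real 550, and the highest other gave 3436, so chance cannot be excluded for that number. The highest other split called 935 genes, which points to a structure of the samples, whose source was not tested.

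The gene w was 1 of these 9, and it was also higher in the mutant at all 6 times, by 4.66 on the log2 scale. The tables argue against more pigment cells or eye tissue in the mutant samples, since the other 18 eye pigment genes had a median log2 fold change of -0.11 (SE 0.15). A candidate explanation is a w transcript driven from near cwo, as from a marker gene carried by an insertion. Over the 12 mutant libraries w followed cwo with Pearson r = 0.974 (permutation p = 1e-05, the smallest possible), closest of 11094 genes, and in wild type r was -0.16 (permutation p = 0.628). Both w and cwo cycle in the mutant, so other genes with an evening peak could follow cwo as well. The control strain is named after a w allele, and the w allele and construction of the mutant line are not given in the sources used here. The difference in w level between the lines therefore cannot be assigned to the cwo mutation. A biological response of the w gene at its own locus stays open and untested.

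Among the gene names 6 were calendar dates, and 87900 counts lay on them, 956 to 4379 per library, above the 3 counts that a count of 0 allows. In every library 4 of the names held more than 3 counts. The genes behind these names cannot be told from the table, and they are part of no comparison.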

How the results depend on the processing

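The settings chosen only after the data were seen are gene length offsets, leaving out the pair of wild-type libraries with the lowest length score, ZT6 to ZT18 alone, leaving out genes at 0 in some libraries and at 10 CPM or more in others, and lists without cwo and w. Counts are compared within a factor of 1.5; no called result reversed, and gene lists whose direction turned were called under neither setting. Except where a setting by its construction tests fewer genes, fewer libraries or a stricter limit, the cause was not tested.

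Of 160 named calls, 114 kept direction and threshold under every alternative run for them and 46 lost the call in at least 1. RLE scaling and the replicate block left all counts within 1.5 times the reported ones. Leaving out genes at 0 in some libraries was run only for the genotype differences over all times and at single times, and left those counts within 1.5 times. RLE scaling kept 97.3% of the all-times calls, DESeq2 99.1%, limma-voom 92.3%, gene length offsets 57.7% (2172 called, 1791 shared) and the fit without the pair of libraries 74.4% (2750 called, 2309 shared).

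The replicate numbers do not pair the samples across genotypes: the correlation of replicate differences exceeded 0.1 in 3 of 15 pairs of wild-type times, in 14 of 15 pairs of mutant times and in 2 of the 6 same-time pairs of wild type and mutant. With a replicate block 3586 genes differed over all times, 3083 of them among the 3104, 2282 differed at ZT2, and 808 were rhythmic in wild type. In the mutant the number therefore follows a shared difference between the libraries, which the block removes only in part since it is fitted for both genotypes together.

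DESeq2 gave higher counts: 26 for the interaction, 1647 and 255 for wild-type and mutant rhythms, 9 for the difference in rhythm, and 2867, 174, 3.1e+02, 208, 186 and 466 at ZT2, ZT6, ZT10, ZT14, ZT18 and ZT22. On simulated counts its false calls were above the level it was set to. Limma on FPKM with a pseudocount of 1, on 8428 genes, gave 2032 genes over all times, 3 for the interaction, 277 and 76 for the rhythms and 282 at ZT2. With a pseudocount of 0.1 these were 1962, 4, 250, 66 and 225, and ZT6 had 59. Limma-voom gave 579 at ZT2. Without the filter ZT2 had 1022 genes, and with a mean CPM of at least 5 ZT6 had 61.

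At an adjusted p under 0.01 there were 1152 genes over all times, 213 and 65 rhythmic ones, and 75, 39, 63, 44, 44 and 61 at ZT2 to ZT22. With a log2 fold change of at least 1 there were 492 over all times and 1064 at ZT2. An amplitude of at least 0.5 left 370 wild-type rhythms. Time as a 6-level factor gave 247 and 70 rhythmic genes. Fitting only the 12 libraries of a genotype gave 128 and 265, with more in the mutant than in wild type, only replicate 1 gave 16 and 9, and only replicate 2 gave 11 in wild type and, in edgeR, 0 in the mutant, where p-values rest on 6 libraries. Only the 4 libraries of a time gave 0 genes at ZT2 and 179, 27, 11 and 23 at ZT6, ZT10, ZT18 and ZT22. Adjusting over genes rhythmic in either genotype, a selection that favours differences, gave 9 differences in rhythm.

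Over ZT6 to ZT18 alone 789 genes differed, 777 of them among the 3104. Gene length offsets gave 1071 genes at ZT2 and 10 called lists. Without the pair of libraries the interaction had 2 genes and the mutant rhythm 250. With an estimated correlation camera called 3 lists, and with neither cwo nor w 0 lists (5 at an unadjusted p under 0.05); with the preset correlation 13 were called without these genes, and fry called 17 with them.

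With an estimated correlation the adjusted p of lists that were no longer called was 0.243 for head rhythm outputs, 0.484 for neuropeptides, 0.437 for glia, 0.0905 for muscle, 0.438 for antimicrobial peptides, 0.142 for heat shock and chaperones, and 0.422 for cuticle proteins. It was 0.644 for fat body and for immune recognition, and 0.674 for glutathione S-transferases, mitochondrial ribosomal proteins, oxidative phosphorylation and proteasome. With neither cwo nor w in the lists, core clock (0.131), pigment cell and lens (0.949) and proteasome (0.0502) lost the call at the preset correlation. Without these genes and with an estimated correlation it was 0.422 for core clock, 0.291 for head rhythm outputs, 0.949 for pigment cell and lens, and 0.279 for evening E-box genes, muscle, and heat shock and chaperones; the other values were those given for the estimated correlation.

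Gene length offsets took the call from core clock and glia (each 0.0564), head rhythm outputs (0.116), neuropeptides (0.286), glutathione S-transferases (0.685), mitochondrial ribosomal proteins (0.158) and proteasome (0.859), and gave it to odorant, gustatory and ionotropic receptors (0.0226). The direction turned, without a call, for neuropeptide and amine receptors (0.686), neuronal and synaptic genes (0.109), P450 genes (0.859), cytosolic ribosomal proteins (0.177) and activity regulated genes (0.866). Over ZT6 to ZT18 female biased (0.0308), male biased (0.0315) and chemoreceptor genes (0.0374) gained a call, while glutathione S-transferases and oxidative phosphorylation (each 0.143), mitochondrial ribosomal proteins (0.253) and proteasome (0.636) lost it. There the direction turned, without a call, for ovary and testis transcripts and odorant binding proteins (each 0.935), P450 genes (0.395), cytosolic ribosomal proteins (0.253) and activity regulated genes (0.913).

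Fry also called phototransduction (0.0256), female biased (0.0423) and male biased genes (0.0027), and not mitochondrial ribosomal proteins or oxidative phosphorylation (each 0.0528). The replicate block called female biased genes (0.0134) and not proteasome (0.0571). Without the pair of libraries proteasome was not called (0.0714), and cytosolic ribosomal proteins turned direction (0.19, not called).

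Leaving out each library in turn gave 1973 to 5592 genes over all times (5592 without wild-type ZT2 replicate 1; 2005, 1973, 1973 and 1993 without mutant replicate 1 at ZT6, ZT14, ZT18 and ZT22), and 0 to 2106 for the interaction (2106 without wild-type ZT2 replicate 1, at most 5 without any other). It gave 383 to 1097 wild-type rhythms (1097, 952, 393 and 383 without wild-type replicate 1 at ZT2, ZT6, ZT14 and ZT22), 86 to 212 mutant rhythms (212 without wild-type ZT2 replicate 2), 0 to 1 differences in rhythm (1 without wild-type ZT14 replicate 2) and 956 to 4798 transcripts (4798 without wild-type ZT2 replicate 1 and 2633 without mutant ZT18 replicate 2; 1060, 1080 and 1063 without wild-type ZT18 replicate 1, ZT6 replicate 2 and ZT14 replicate 2; 956 to 1036 without a mutant library of replicate 1).

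At single times a left-out library leaves 1 in its group, which is assumed to vary like the other groups. The counts were then 66 to 5734 at ZT2 (5734 and 97 without wild-type replicates 1 and 2, 66 and 80 without the mutant ones), 27 to 42 at ZT6 and 37 to 59 at ZT14, where each of the 4 libraries moved the count by over 1.5 times, and 48 to 103 at ZT10 (48 without wild-type replicate 1, 55 and 73 without the mutant ones). They were 42 to 71 at ZT18 (42 without wild-type replicate 2, 48 and 47 without the mutant ones) and 47 to 246 at ZT22 (63 without wild-type replicate 1, 47 and 246 without mutant replicates 1 and 2).

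On simulated counts 29% of changes of 1 on the log2 scale were found at ZT2, against 85.5% over all times, and 81% of changes of 2, against 96.5%. A rhythm of amplitude 0.5 lost in the mutant was found for 11% of genes.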

Other observations

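Chosen only after the result was seen were the test for overlapping gene models and the fold changes at ZT2 without each library, and the interaction shares with all libraries and without each library other than wild-type replicate 2; the tests of a library that stands apart, of gene length, of the interaction at ZT2 and of the segment around cwo were set before their results, as were the splits.

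Many more genes were called at ZT2 (1609) than at the other times (84 to 140), and the tables argue against gene length bias as the whole cause, since with gene length offsets 1071 genes were called there, 784 of them among the 1609, and 118 to 168 at the other times. A single library that stands apart and a genotype effect that is larger at ZT2 cannot be told apart here. The wild-type ZT2 replicates differed most from each other (chi-square per degree of freedom 314, against 34.8 to 124 in the other groups). Counts from fits without 1 library cannot decide, since such a fit leaves 1 library in a group. Each library left out at ZT6 or ZT14 lowered the count there too. Without wild-type ZT2 replicate 2, 97 genes were called, but leaving out a mutant library gave 66 or 80, where the prediction for a single library had been that most calls would stay. The median log2 change of the 1459 genes called at ZT2 alone, in its reported direction, was 1.16 with all libraries. It was 1.12 and 1.20 without mutant replicates 1 and 2, and 1.66 without wild-type replicate 1. Without wild-type replicate 2 it was 0.55, and 98.5% of the genes had the same direction. The genes were selected on these same libraries, which favours a shared direction and large changes, so these values do not test an effect at ZT2. For the genotype effect, 3.7% of the 1459 genes had an interaction p under 0.05 without wild-type ZT2 replicate 2, under the bound of 10% set beforehand, but that bound was wrong, since with all libraries the share was only 7.4% (75.2% without wild-type replicate 1, 3.2% and 3.0% without mutant replicates 1 and 2).

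Genes that changed at least 2-fold were more frequent near cwo. Of the 443 tested genes within 2000000 bases of it, 8.13% (36 genes) changed at least 2-fold, against 4.27% of the other genes (Fisher's exact test, two-sided, p = 5.3e-04). A candidate explanation is a chromosome segment of another origin around cwo in the mutant line. Windows of as many genes were drawn along every chromosome with enough genes, those around cwo included. Of these, 11.2% reached this share. Windows around cwo can raise that figure, and it was not computed without them. It therefore cannot tell a segment from a run of changed genes of any other cause, and no variants could be read from these files. Named genes within 2000000 bases of cwo include CG8147, CG12947, MtnA, CG4757, tws, Dh44, RpL24-like, GstZ1, GstD9, GstD11, Ugt86Dd, Ugt86Dg and Ugt86Di. Whether their changes come from the cwo mutation or from such a segment was not tested. An effect of cwo on its neighbours stays open and untested.

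The number of genes that differed between the genotypes over all times exceeded that of every other split tested: 1 of 80 splits, the real one, gave 3104 genes, and the highest other gave 15. For transcripts it was also 1 of 80 (1676 against 49). The splits treat libraries as independent, while replicate differences correlated over 0.1 in 14 of 15 pairs of mutant times. Other splits also leave the real genotype difference in the spread, which lowers their counts. The splits therefore cannot separate an effect of cwo from another difference between the lines or their cultures. For gene lists 4 of 80 splits gave as many calls, 16 in the real split and 16 in the highest other, so chance cannot be excluded for that number. When the times were dealt out again to the libraries within each genotype, 1 of 80 orders, the real one, gave 623 rhythmic genes in wild type (highest other 120), and 1 of 80 gave 121 in the mutant (highest other 2).

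Of the tested genes, 90 were at 0 in some libraries and at 10 CPM or more in others, and 18 of them differed between the genotypes over all times. For 50% of them an overlapping gene model gained at least 50% of their level where they were at 0, against 29.9% of other genes of like level. When the counts of overlapping models were added, 31.1% kept their switch.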
